A study of Mus musculus and Gallus gallus
Mus musculus with 42 samples.

How the data were processed

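The series profiled mouse cells by droplet-based single-cell RNA sequencing, with 42 samples described by the labels used here. The labels place 9 samples on the inDrop platform and 33 on 10X Genomics chemistry. The tools Cell Ranger, STAR and Seurat (versions 3 and 3.1.5 are named for part of the samples) and the genome builds mm10 and hg38 are listed in the submitters' processing notes, without the role of each. No expression values were analysed here, so read depth per sample is unknown in this text. No test between sample groups was made, and the question each such comparison addresses is left open.

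The analysed data were a pair of gene annotations in GTF layout, one with records for factors and tdTomato added and one with a record for human LIN28A added. The values used were the first and last base of each annotated feature, other coordinates being derived from them. They carry no normalization. These coordinates were deposited by the authors as a mouse annotation on GRCm38.p6, per the file headers. The added records carry the source word Transgene, per the deposited records. Whether the mouse records were filtered and how the added sequences were built is not given in the sources used here.

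All positions below are 1-based on GRCm38. Of the 22623 mouse genes in the deposited annotation, 22590 were found by identifier in GENCODE release M21, and 99.3% of those had the same chromosome, strand, first and last base there. GENCODE was used only for this check and to count overlaps with all of its genes. These include gene types that the deposited annotation analysed here did not hold.

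The annotations were compared record by record as whole lines and then by gene identifier. For each gene, the 3′ end was defined as the last 500 exonic bases of every transcript, joined. Sequencing of this kind reads the 3′ part of transcripts. A base that exons of another gene also cover on the same strand cannot be assigned to one gene by position alone. Exons on the other strand leave this doubt only where reads lose their strand, which was not checked here. The share of 3′ bases covered by exons of another gene was measured on the same strand and on the other strand. The longest 3′ UTR of a gene was the largest sum of annotated 3′ UTR bases in any of its transcripts. Of the protein-coding genes, 803 had no annotated 3′ UTR and were left out of that measure, which leaves 21123. Coding length is the longest annotated coding sequence with its stop codon.

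Gene lists were fixed before the data were examined. They cover the reprogramming factors (4 genes), limb progenitor genes (26), posterior Hox genes of clusters A and D (10), limb signalling genes (18), chondrogenic genes (13), fibroblast and matrix genes (15), skeletal muscle genes (8), endothelial and blood genes (11), epithelial genes (8), neural crest genes (6) and let-7 microRNAs (12). The posterior Hox list also holds Hoxd8, which is not usually counted among the posterior genes. The text names all factors and all genes of that list. Of the let-7 microRNAs it names 4 as examples. Of each other list it names the 2 members with the longest and the 1 with the shortest longest 3′ UTR, and up to 3 with the largest same-strand share. Some genes that the rule selects are not reported here. Genes named outside this rule are said to be so.

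Each list was compared with 10000 random lists of the same size drawn from protein-coding genes. Two-sided p-values came from this permutation, with Benjamini-Hochberg adjustment over the 10 lists with records, separately for each measure, and a threshold of 0.05. The smallest p it can give is 0.0002. Matched random lists replaced each member by a gene of the same stratum, of up to 20, in transcript number or in distance to the nearest gene on the same strand. Genes are not independent replicates, so these tests describe the annotation and not the samples. The test was tested on simulated data, with lists of 20 genes drawn from the 21123 lengths. Of 200 such lists with unchanged lengths 5.5% passed an unadjusted threshold of 0.05, of 200 with doubled lengths (factor 2) 68.5%, and of 200 with tripled lengths (factor 3) 92%. Lists as short as the 4 factors were not simulated.

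The alternatives were windows of 300 and 1000 bases, overlap only with protein-coding genes or with protein-coding and lncRNA genes, only transcripts tagged basic, a share of at least 50%, the median 3′ UTR over a gene's transcripts, and the other annotation. Overlap with all GENCODE genes and the tests of all list members pooled and without the globin genes were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.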

Results

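The study followed mouse fibroblasts from outside the limb as they were driven towards limb progenitor cells, beside limb progenitors taken from embryos. The labels name the introduced factors as Prdm16, Zbtb16 and Lin28a (3 factors), with Lin41 as the addition in the set of 4. Prdm16 and Zbtb16 are zinc finger transcription factors. Lin28a is an RNA-binding protein known to block let-7 microRNA maturation. Lin41, whose mouse gene symbol is Trim71, is a known let-7 target. Of the 42 samples, 31 fall into 22 groups that each hold 1 condition, and 8 of those groups have 2 or more samples. Among these 8, the embryonic limb group at E10.5 joins an inDrop and a 10X library. Another holds libraries from leftover droplets of xenografted limb progenitors, which are not a condition independent of those xenografts. A further 9 samples in 7 groups pool several conditions in 1 capture. The labels of 2 samples contradict themselves on culture day or format, so these stay without a group.

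The embryonic samples comprise limb mesenchyme at E9.5, E10 and E10.5 and forelimb field mesenchyme at E9.0. Embryonic limb progenitors were also cultured in Matrigel or 3D limb culture for up to 14 days, mostly within multiplexed samples. The reprogrammed samples were grown in 3D, in hyaluronan for 14 days, in Matrigel for up to 14 days, or in what later labels call 3D limb culture for up to 14 days. Of the multiplexed samples, 2 also hold cells from day 2 in 2D limb culture. The hyaluronan samples with 3 factors are labelled Prx1-EGFP positive or Prx1-EGFP negative. Control fibroblasts are labelled as carrying an empty vector, as given a control infection, or only as controls, and 1 sample holds fibroblasts from ordinary 2D culture. Xenografts into chick wings were sampled as 3 batches of reprogrammed cells and 2 batches of fresh limb progenitors, and 2 more libraries came from droplets left over from the latter. Expression values of these samples were not analysed here. The results below therefore concern the deposited annotations themselves, and whether positions in them separate the genes that the design is about. The labels do not state that transcripts of a given sample were named against them.

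The added records show which introduced sequences had a record of their own in these annotations. Whether reads could be counted against them was not tested. The annotation with factors and tdTomato carried 6 added genes. They were hPLZF (2022 bases; PLZF is the human name for ZBTB16), hLin41 (2703 bases), rtTA (747 bases), WPRE (1664 bases), EGFP (2903 bases) and TDTOMATO (1431 bases). rtTA is the transactivator of doxycycline-controlled promoters, and WPRE is a viral RNA element commonly placed in lentiviral vectors. EGFP and tdTomato are fluorescent reporters. The other annotation carried 2 added genes, hLin28a (987 bases) and EGFP (740 bases). Each added gene was a single-exon plus-strand record that began at base 1 of a sequence named after it. None of the added records analysed here bore the name of Prdm16.

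The annotations were otherwise the same text. They shared 1711137 records line for line, and 24 records differed, 18 in the annotation with factors and tdTomato and 6 in the one with human LIN28A. By identifier, 5 genes occurred only in the former and 1 only in the latter. EGFP occurred in both under 1 name but was 2163 bases longer in the former. The added records analysed here held no hLin28a beside hPLZF and hLin41, and hLin28a stood in an annotation without hPLZF, hLin41 and TDTOMATO. Some library names in the labels contain mm10 or tdtomato, but the labels do not state which annotation served which sample.

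The mouse factor genes lay on chromosomes 4 and 9, all on the minus strand. Prdm16 (ENSMUSG00000039410) spans chromosome 4 from 154316125 to 154636873, with 13 transcripts, and Lin28a (ENSMUSG00000050966) spans 134003330 to 134018841, with 4. Zbtb16 (ENSMUSG00000066687) spans chromosome 9 from 48654297 to 48836222, with 2 transcripts, and Trim71 (ENSMUSG00000079259) spans 114507133 to 114564369, with 1. The hPLZF record was exactly as long as the mouse Zbtb16 coding sequence, 2022 bases with the stop codon. The hLin41 record exceeded the 2568 coding bases of Trim71 by 135, and the hLin28a record exceeded the 630 coding bases of Lin28a by 357.

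**Figure D1:**
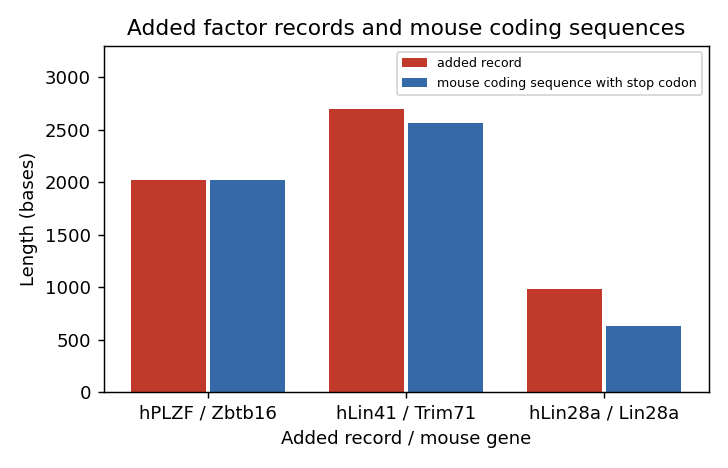
Length in bases of each added factor record (red) and of the longest mouse coding sequence of the matching gene with its stop codon (blue); bars are single annotated lengths without error. The hPLZF and Zbtb16 bars are both 2022 bases, while hLin41 and hLin28a exceed their mouse counterparts by 135 and 357 bases.

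The mouse factor genes carried long annotated 3′ UTRs. These were 4785 bases in Prdm16, 2845 in Zbtb16, 2775 in Lin28a and 5512 in Trim71. All 4 exceeded the median of 1088 bases over 21123 protein-coding genes. Their median of 3815 bases lay above 99.2% of the medians of random lists of 4 genes. It did not pass the threshold after adjustment (permutation p = 0.0162, adjusted p = 0.081, two-sided, 10 lists). With the median over each gene's transcripts in place of the longest, the list median was 3719 bases and passed (adjusted permutation p = 0.012). The list median itself was lower there, while the median over all protein-coding genes fell from 1088 to 711 bases. Random lists matched on transcript number were not run for that measure. None of the 4 shared a 3′ base with another gene of the deposited annotation on either strand. Against all GENCODE genes, a comparison added after seeing the data, Lin28a had 16.1% of its 3′ bases opposite Gm13061.

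The posterior Hox genes, which pattern the limb along its axes, had 3′ ends free of other genes' exons in the deposited annotation. Hoxa10 (chromosome 6, 52231197 to 52240854) lies 107 bases from Hoxa9 (52223100 to 52231089), and neither gene's exons covered the 3′ end of the other. Hoxa11 (52242106 to 52245810) and Hoxa13 (52257694 to 52260880) followed on the same strand. On chromosome 2 the order was Hoxd13 (74668310 to 74671599), Hoxd12 (74675013 to 74677705), Hoxd11 (74679557 to 74687016), Hoxd10 (74691924 to 74695105), Hoxd9 (74697727 to 74700208) and Hoxd8 (74704615 to 74707933). Of these 10 genes, 0 shared 3′ bases on the same strand and 0 on the other strand (random lists of 10 had a median of 0 on the same strand and 1 on the other; adjusted permutation p = 1 for each). Random lists matched on the distance to the nearest gene on the same strand had a same-strand median of 1 (range 0 to 2, unadjusted permutation p = 0.72). That comparison decides nothing. The 10 genes overlap no other gene on the same strand, which sharing requires, so the matching variable already fixed their count. Against all GENCODE genes, 26.6% of the 3′ bases of Hoxd11 and 4.55% of those of Hoxa9 were shared on the same strand.

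Annotated 3′ UTRs of the posterior Hox genes had a median of 1177 bases, inside the random range of 403 to 2311 (adjusted permutation p = 0.916). The values were 1653 bases for Hoxd12, 1463 for Hoxd13, 1309 for Hoxa10, 1254 for Hoxa11, 1210 for Hoxa13, 1144 for Hoxa9, 1121 for Hoxd8, 787 for Hoxd9 and 737 for Hoxd10. Hoxd11 stood apart at 30 bases, and 0.833% of protein-coding genes with a 3′ UTR had one as short. Its protein-coding transcript ended at 74684168, and a second transcript of the gene, typed lncRNA, ran on to 74687016.

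**Figure D2:**
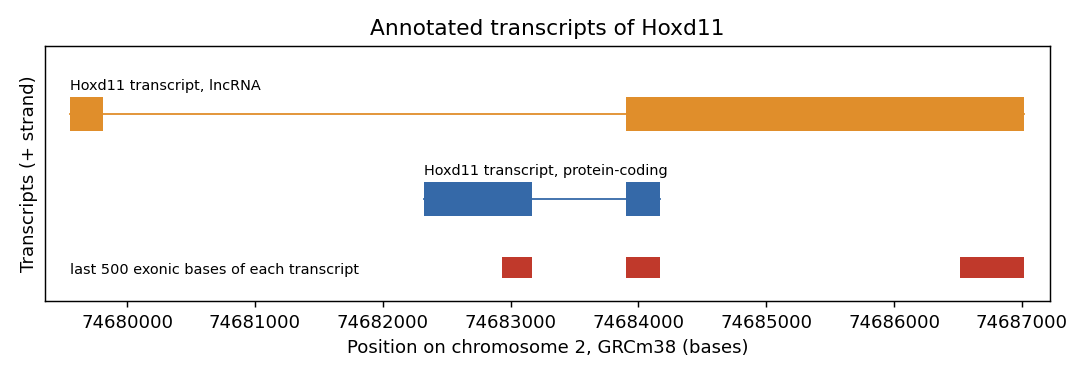
Annotated transcripts of Hoxd11 against position on chromosome 2 (GRCm38, bases), with exons as boxes, the protein-coding transcript in blue, the lncRNA-typed transcript in orange and the last 500 exonic bases of each transcript in red. The coding transcript ends at 74684168 and the other at 74687016.

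Limb progenitor genes were the longest list, and their 3′ ends were likewise unshared in the deposited annotation. Of 26 members, 0 shared 3′ bases with another gene on the same strand and 0 on the other strand, and with all GENCODE genes these counts were 1 and 4. In the deposited annotation, random lists of 26 had a median of 1 on the same strand (range 0 to 3) and 2 on the other (range 0 to 6). The list lay inside both ranges. Meis1 (5687 bases), a homeodomain transcription factor of the proximal limb, had the longest 3′ UTR, and Prrx2 (321 bases), a paired-related homeobox gene, the shortest. The median was 1319 bases, against a random range of 576 to 1836 (adjusted permutation p = 0.801). Among limb signalling genes the longest 3′ UTRs were those of the Hedgehog receptor Ptch1 (9012 bases) and of Wnt5a (4508 bases). The shortest was that of Gli1 (165 bases), a transcription factor of the same pathway. Their median of 1338 bases was also inside the random range of 514 to 2007 (adjusted permutation p = 0.801).

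Genes of the fibroblast start point and of cartilage, the tissue that limb progenitors can form, had list medians of 752 and 823 bases. Neither differed from random lists (adjusted permutation p = 0.801 for each). Pdgfra (3115 bases) and Twist2 (1885 bases) had the longest fibroblast 3′ UTRs. S100a4, a calcium-binding protein used as a fibroblast marker, had the shortest (141 bases). Sox6 (6046 bases) and Sox5 (4839 bases), cofactors of Sox9, had the longest of the chondrogenic list, and the cartilage matrix gene Comp (277 bases) the shortest.

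S100a4 was the single member of all lists that shared 3′ bases with another gene on the same strand. It spans chromosome 3 from 90603771 to 90606045, and 51.7% of its 584 3′ bases were also exons of Gm42674 (90601904 to 90605885). These 584 bases are all exonic bases of this short gene, so the share is not limited to its 3′ part. The only Gm42674 transcript is typed as a target of nonsense-mediated decay. The last 160 bases of S100a4 lay beyond it and were not shared. Over all lists 1 of 119 members had such sharing (0.84%), against 861 of 21926 protein-coding genes (3.93%). Random lists of 119 gave a median of 5 (permutation p = 0.099, adjusted p = 0.229 over 3 pooled tests), so the difference did not pass the threshold. With all GENCODE genes allowed to overlap, 4 members (3.36%) and 1226 protein-coding genes (5.59%) shared 3′ bases. When at least 50% had to be shared, the counts were 1 (0.84%) and 443 (2.02%).

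Overlap with a gene on the other strand was seen for 6 of 119 members (5.04%), against 2004 of 21926 protein-coding genes (9.14%; permutation p = 0.152, adjusted p = 0.229). The counts were 16 (13.4%) and 3353 (15.3%) with all GENCODE genes, and 0 and 214 (0.976%) when at least 50% of the 3′ bases had to be covered. These 6 genes are named because of their values. Rarb, a retinoic acid receptor, had 40.3% of its 3′ bases opposite exons of Top2b. Gdf5 had 8.2% opposite Gm15557, Tagln 7.89% opposite Pcsk7, Bmp4 6.74% opposite Gm15217, Col10a1 3.6% opposite Nt5dc1 and Gli1 3.49% opposite Arhgap9. With all GENCODE genes, the share of Tagln was 69.8%, opposite Gm48529 and Pcsk7 together. No single list passed the threshold for either strand (adjusted permutation p = 1 for each).

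Markers of other cell types that a dissociated limb could hold gave the only list that passed. The endothelial and blood list had a median 3′ UTR of 158 bases over 11 genes, below all but 0.01% of random medians (range 397 to 2273; permutation p = 0.0004, adjusted p = 0.004). Kdr (1596 bases) and Cdh5 (1513 bases), both endothelial surface proteins, were the longest and the alpha globin Hba-a1 (74 bases) the shortest. The 5 globin genes, set apart after their values were seen, ranged from 74 to 132 bases, and without them the median of the other 6 was 1039 bases and the list no longer passed (unadjusted permutation p = 0.882). Medians were 933 bases for skeletal muscle genes, 513 for epithelial genes and 1058 for neural crest genes, and none of these passed (adjusted permutation p = 0.916, 0.54 and 0.916). The muscle list ran from Pax7 (3725 bases) and Pax3 (2038 bases) down to Actc1 (184 bases). The epithelial list ran from Trp63 (3064 bases) and Sp8 (2704 bases) down to Krt18 (66 bases). The shortest of the neural crest list was that of Tubb3 (391 bases).

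**Figure D3:**
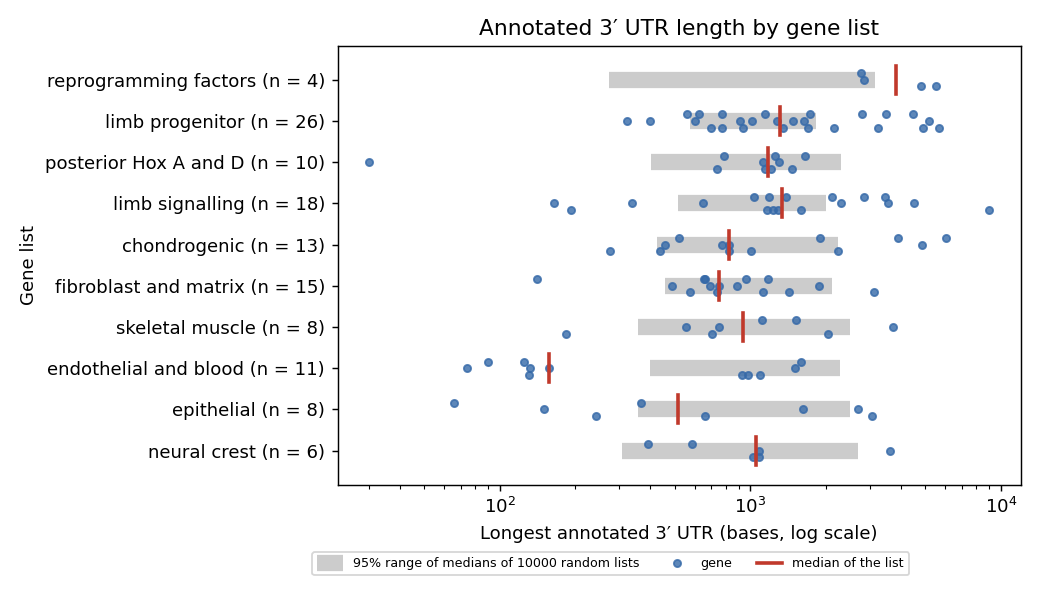
Longest annotated 3′ UTR in bases (log axis) for each gene of the 10 lists (blue points, spread vertically for legibility), the list median (red bar) and the central 95% range of medians of 10000 random lists of that size (grey). The endothelial and blood median of 158 bases and the factor median of 3815 bases lie outside their grey ranges, and the latter did not pass after adjustment.

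The gene types of the annotation limit which limb transcripts have a record in it. The 22623 mouse genes analysed here were 21926 protein-coding genes and 697 immunoglobulin and T cell receptor segments, pseudogenes included. Of the 12 let-7 microRNA genes on the list, among them Mirlet7a-1, Mirlet7b, Mirlet7g and Mir98, 0 had a record among those analysed here. Whether libraries of this kind could capture these microRNAs was not tested. Within the protein-coding genes, 57.9% of 102208 transcripts were typed protein-coding, 21% retained intron, 13.9% lncRNA and 7.04% nonsense-mediated decay.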

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

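Overlap with all GENCODE M21 genes, an alternative chosen after seeing the data, raised the list members with a 3′ end shared on the same strand from 1 to 4 and those overlapped on the other strand from 6 to 16. The partners gained by list members were all of gene types that the deposited annotation analysed here did not hold, mostly antisense or processed transcripts. Asking for at least 50% of the 3′ bases left 0 members on the other strand and 1 on the same strand, while the protein-coding genes with same-strand sharing fell from 861 to 443. Comparing gene identifiers in place of whole lines gave 6 differences instead of 24. The other planned settings kept the members' counts and pooled median within 1.5 times, but the median over all protein-coding genes went from 1088 to 711 bases with the median over transcripts. Limiting overlap to protein-coding genes, or to these and lncRNA genes, was the same setting here, as no lncRNA genes were analysed, and removed only immunoglobulin and T cell receptor segments. The other annotation has the same mouse records. Neither setting tests stability. No list passed on overlap under any setting, which says little because most lists held 0 such members in the deposited annotation. For the 3′ UTR, basic transcripts and the median over transcripts left each list on its side of the threshold except the factor list, which passed with the latter (3719 bases, adjusted permutation p = 0.012). No paired analysis was possible because no value belonged to a sample. For the same reason leaving out replicates and other normalizations were not run, and read depth does not enter these results.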

Other observations

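The tests on globin genes, on Hoxd11 and on genes with short 3′ UTRs, and the GENCODE overlaps, were chosen after the result was seen; the test matched on transcript number was fixed before. Several limb genes have a partner in GENCODE M21 that the deposited annotation analysed here did not hold. On the same strand, 26.6% of the 3′ bases of Hoxd11 were exons of the processed transcript Gm28309, 6.1% of those of Pitx1, a hindlimb transcription factor, were exons of the lincRNA Gm28760, and 4.55% of those of Hoxa9 coincided with the microRNA gene Mir196b. On the other strand, 10 list members that had no partner in the deposited annotation gained one. Tagln, which had Pcsk7, gained Gm48529 as well, and its share rose from 7.89% to 69.8%, the largest of the list members on that strand. Hand2, a posterior limb transcription factor, had 20% of its 3′ bases opposite Hand2os1, Sall4 had 21.8% opposite Gm14261, Lin28a had 16.1% opposite Gm13061 and Wnt5a had 15% opposite Gm2670. These genes were chosen as examples after their values were seen.

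The short 3′ UTRs of the endothelial and blood list were still outside the range when random lists were matched on the number of transcripts per gene (two-sided permutation p = 0.0009999), so that number alone does not account for them. Without the 5 globin genes the median of the remaining 6 was 1039 bases and no longer outside (permutation p = 0.882). A candidate explanation is that the list stands apart through its globin genes; these were picked because they were short, and no biological explanation was tested.

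The 30-base 3′ UTR of Hoxd11 may reflect how its transcripts were typed: 2848 exonic bases of the gene lie downstream of the end of its protein-coding transcript, all in the lncRNA-typed one. This was seen before it was tested, so it cannot decide the explanation. Reads there still fall within the Hoxd11 gene. A comparison over all genes could not decide this for short 3′ UTRs in general. Among genes with a 3′ UTR and a transcript typed protein-coding, 974 had at most 100 bases. Of these, 1.13% had 500 or more such downstream bases, against 2.43% of the other 20058 (Fisher's exact test, two-sided, p = 0.00667). The longest 3′ UTR was taken over all transcripts, including those typed nonsense-mediated decay. Such a transcript can supply both the downstream bases and a longer 3′ UTR. A gene of this kind then counts among the longer ones, so the direction is partly built in.

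The EGFP record was 2903 bases in one annotation and 740 in the other, a difference of 2163 bases. What the longer one holds besides the reporter was not tested, since the added sequences were not used here. Counts under the name EGFP from both annotations would cover different lengths.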
